A study of Arabidopsis thaliana with 6 samples.

How the data were processed

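Total RNA of whole rosettes was biotin-labelled and hybridised to Affymetrix Arabidopsis Genome GeneChip arrays, per the labels' protocols. The 6 samples fall into wild type and 35S:PCO1, with 3 replicates each, by the genotype label. The sample titles of the overexpressor name CDO1 in place of PCO1, while the genotype, the description and the series text name PCO1, which is used here. The plants grew with 8 h of light and 16 h of darkness at 22 °C by day and 18 °C by night and were harvested 2 h after the start of the day. Their age is given as 4 weeks in the sample characteristics and as 5 weeks in the RNA protocol, per the labels.

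The authors deposited log2 values, 1 per probe set and array, made with RMA (background correction, quantile normalization between arrays and summary over the probes of a set), per the submitters' processing notes, which give no version. Whether the 6 arrays were summarised alone or with others is not given in the sources used here. RMA gives a value to every probe set, with no detection call, and forces the distributions of the arrays together, so a change of total RNA per cell would not show. The values were used as deposited, and their range fits a log2 scale. No column of the table was left without a sample. The number of arrays limits the precision: the median SE of a difference was 0.0648, and the median SD over replicates was 0.0752 in wild type and 0.0661 in 35S:PCO1. As a floor of the signal, the 12 probe sets for the bacterial genes dap and lys lay between 3.07 and 3.82. Some other bacterial controls lay higher, such as AFFX-PheX-3_at with means of 5.73 in wild type and 5.86 in 35S:PCO1.

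Of 22810 probe sets, 64 Affymetrix controls were left out of the main test. The remaining 22746 were named through GEO's platform annotation, in which 13513 had 1 gene, 503 had several and 8730 had none; 13436 of the first were updated through the NCBI RefSeq gene table of assembly TAIR10.1, used only for names. No coordinates are given, as no genome build is named for these values. A probe set without a gene there is unnamed here, not without a gene. Many well-studied genes, PCO1 and PCO2 to PCO5 among them, are unnamed in this way, so the planned check of the PCO1 level was not run. List members that the annotation names only by locus are given by locus.

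Groups were compared with limma 3.58.1 (lmFit and eBayes with a constant prior, prior degrees of freedom 5.35) in R 4.3.3, with no covariate, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 64 controls were fitted and adjusted on their own. With 3 arrays against 3, an exact permutation test of 1 value cannot give a p below 0.1. The text names the 12 largest rises and 12 largest falls among changed probe sets with exactly 1 named gene and groups that do not overlap (23 and 64 qualified), and of each gene list up to 4 members with the smallest p. PCO1 and the other PCO genes were to be named in every case. Probe sets and genes outside this rule are said to have been chosen after their values were seen, or stand as members of a list count.

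A set of 24 gene lists with 393 entries (374 distinct genes) was written from textbook knowledge before the data were examined, as were the tests, the naming rule and the alternative settings. Of the distinct genes, 71 were measured by a probe set of their own. A gene with several probe sets was represented by that with the highest mean over all arrays. Lists with at least 3 measured members (9 of them) were tested with camera at a preset correlation of 0.01 against the other genes among 13356, with adjustment over the 9. Entries whose locus carries another symbol in the annotation (2 of them) were left out. The lists cover core hypoxia genes, fermentation, the ERF-VII and N-degron pathway, cysteine and sulfate metabolism, glucosinolates, other PCO genes, heat shock, salicylate, jasmonate, ethylene, cold and abscisic acid, the clock, oxidative stress, photosynthesis, flavonoids, nitrate and phosphate, iron, sugar starvation, touch and wounding, senescence, root, flower and seed markers, and reference genes.

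The procedure was tested on simulated data with the means and spreads of these 22746 probe sets. It recovered 71.2% of simulated changes of 0.5 on the log2 scale, 95.5% of those of 1 and 100% of those of 2, and 2.69% of its calls were not simulated. The 1 list moved was called, and 0 of 6 lists that share no moved gene were. The simulated noise was independent between probe sets. The simulation thus cannot show how the list test or the rate of false calls fares where genes vary together. The alternatives were filters that drop the dimmest 20% or 40% of probe sets, median centring, quantile and cyclic loess normalization, a trended robust prior, array weights, an ordinary t statistic, the replicate number as a block, other thresholds, leaving out each array in turn, and for the lists an estimated correlation, fry and the mean over a gene's probe sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.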

Results

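Transcript levels were measured in whole rosettes of Arabidopsis thaliana kept in air (normoxia), in wild-type plants and in plants of the genotype 35S:PCO1. PCO1 is plant cysteine oxidase 1, an oxygen-dependent enzyme that oxidises the N-terminal cysteine of group VII ethylene response factors and so marks these activators of the hypoxia response for degradation. The 35S promoter, from a plant virus, drives a transgene in nearly all tissues. The comparison asks which transcripts differ when PCO1 is overexpressed while oxygen is plentiful. Each group had 3 samples, each hybridised to 1 Affymetrix Arabidopsis GeneChip, and 22746 probe sets were tested after 64 control probe sets were set aside. The array medians lay between 6.11 and 6.15 on the log2 scale. Correlations across probe sets were 0.996 to 0.999 between arrays of one group and 0.995 to 0.997 between arrays of different groups. The arrays did not separate cleanly by genotype. Wild-type replicate 1 had a lowest correlation of 0.9957 within its group and a highest of 0.9974 with a 35S:PCO1 array. Within 35S:PCO1 the lowest was 0.9977. The sources used here do not say whether the replicates were separate plants or pools, so the p-values measure the spread between these samples, which may be technical.

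The largest fall among named genes in 35S:PCO1 rosettes was that of AT1G62500, which encodes a lipid transfer-type protein. Its signal was 6.15-fold lower, at 8.34 ± 0.67 in wild type and 5.72 ± 0.52 in 35S:PCO1 (log2, SD, n = 3 each). The largest rise among named genes was that of AT1G43590, 3.51-fold higher in 35S:PCO1. GH9B13 (an endoglucanase), TBL36 (a TRICHOME BIREFRINGENCE-LIKE protein, of a family that acetylates wall polysaccharides) and EXPA4 (an expansin, which loosens cell walls) fell, while PME61 (a pectin methylesterase) rose. In all, 191 probe sets changed, which is 0.840% of those tested. Of these, 47 were higher in 35S:PCO1 and 144 lower, so that 75.4% of the changes were falls.

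Most changes were small. The median rise was 0.36 and the median fall -0.49 on the log2 scale, and the smallest change called was 0.27 in size. A change of 2-fold or more was seen for 2 probe sets that rose and 19 that fell. The annotation used here names 1 gene for 87 of the changed probe sets (23 higher, 64 lower), several genes for 2 and none for 102. In all 191, the 3 arrays of one group lay entirely above or below the 3 of the other. Of all tested probe sets 4182 (18.4%) had such groups, where chance gives 10%.

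**Figure D1:**
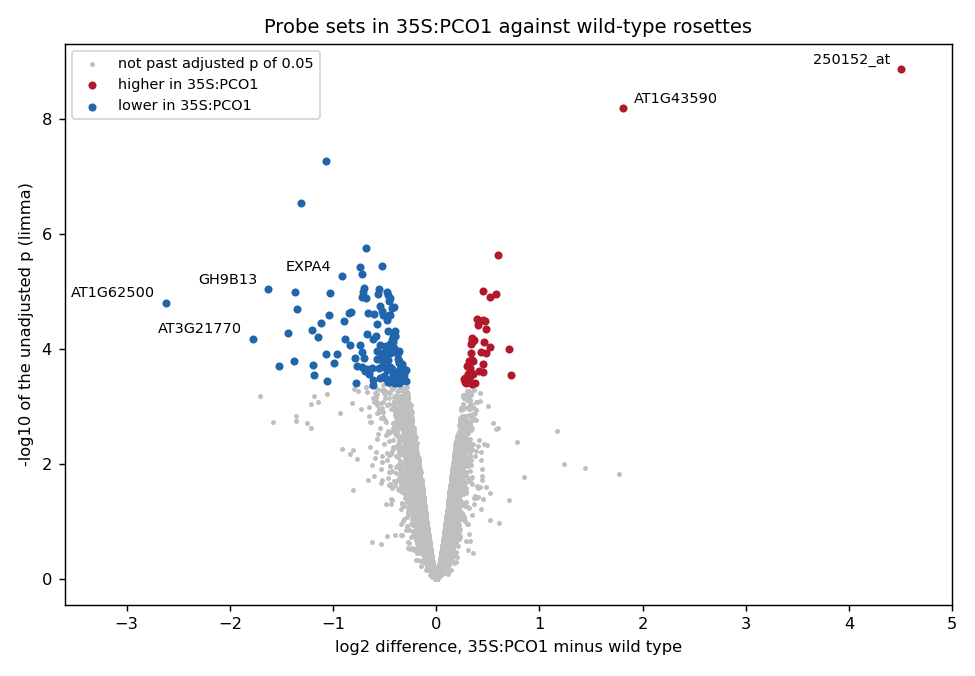
Log2 difference of each tested probe set (35S:PCO1 minus wild type, x axis) against -log10 of its unadjusted p from limma (y axis). Red points are the 47 probe sets that were higher and blue points the 144 that were lower at an adjusted p under 0.05, and grey points are the rest, with 250152_at farthest to the right at 4.50.

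After AT1G62500 (-2.62, SE 0.32, limma adjusted p = 0.0131), the next largest falls were those of the peroxidase gene AT3G21770 (-1.78, SE 0.26, adjusted p = 0.0230) and GH9B13 (-1.63, SE 0.19, adjusted p = 0.0116). AT2G19970, of the family of pathogenesis-related protein 1, fell by 1.43 (SE 0.20). AT3G18280, a further lipid transfer-type gene, fell from 8.52 ± 0.40 in wild type to 7.32 ± 0.16 in 35S:PCO1 (log2, SD, n = 3 each). AT3G45160 fell by 1.19 (SE 0.20) and AT2G28790, an osmotin-like gene, by 1.14 (SE 0.17). TBL36 fell by 1.12 (SE 0.15, adjusted p = 0.0170) and EXPA4 by 0.91 (SE 0.10, adjusted p = 0.0116). AT4G10270, of a wound-responsive family and a member of the core hypoxia list, fell by 0.99 (SE 0.16, adjusted p = 0.0330). With a trended robust prior, AT1G62500, AT3G21770, AT2G19970, AT3G18280, AT3G45160 and AT2G28790 were no longer called (adjusted p from 0.0626 to 0.152). The bHLH transcription factor gene AT1G05710 fell by 0.96 (SE 0.15) and the aspartyl protease gene AT5G07030 by 0.90 (SE 0.12). All these genes also varied together within wild type, with signals that rose from replicate 1 to 2 to 3 (7.64, 8.41 and 8.98 for AT1G62500). They are therefore not independent results.

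Apart from that of AT1G43590, the named rises were smaller than each of the falls above. AT1G43590 rose by 1.81 (SE 0.09, adjusted p = 7.26e-05), followed by AT2G33850 with 0.73 (SE 0.13) and QQS, an orphan gene linked to leaf starch content, with 0.70 (SE 0.11, adjusted p = 0.0272). AT1G79770 rose by 0.60 (SE 0.06). AT3G61840, AT2G38300 and the chitinase family gene AT4G01700 each rose by 0.45, with SEs of 0.05, 0.06 and 0.08. PME61 rose by 0.44 (SE 0.07, adjusted p = 0.0272) and AT5G25840 by 0.41 (SE 0.06). The rises of AT1G52200, of the glutathione S-transferase gene GSTU26 and of AT5G07580, a transcription factor gene of the ERF family, were 0.38 (SE 0.07), 0.36 (SE 0.06) and 0.35 (SE 0.05).

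**Figure D2:**
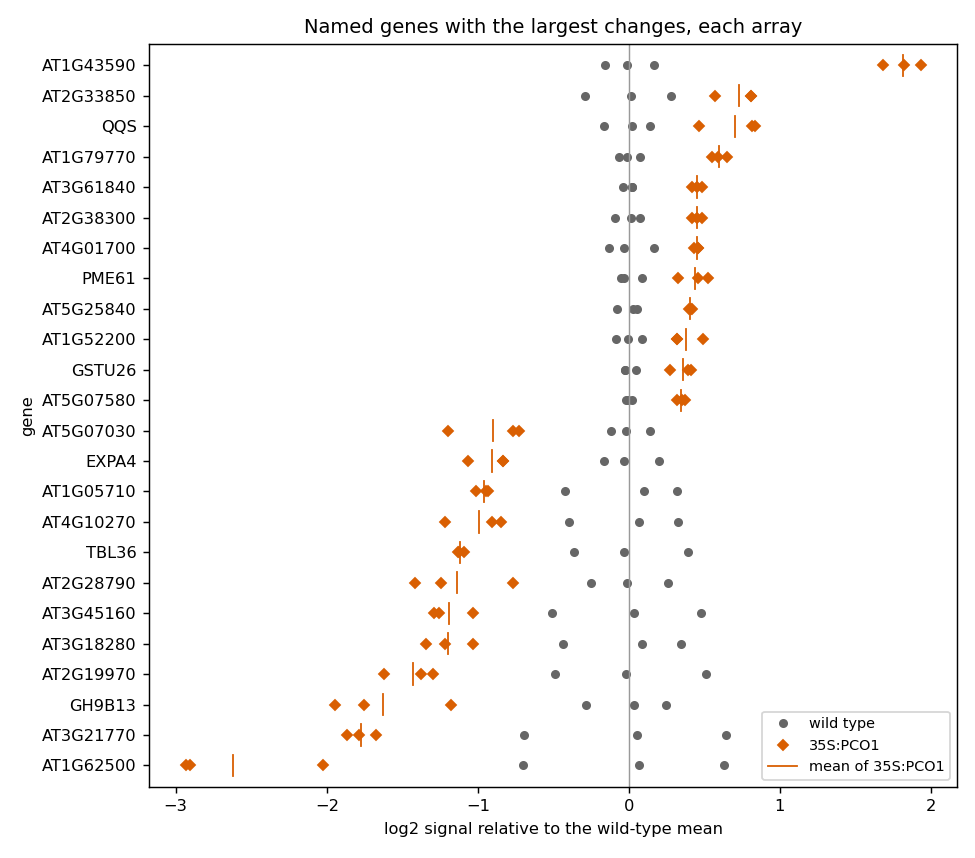
Log2 signal of each array relative to the wild-type mean (x axis) for the 12 largest rises and 12 largest falls among named genes (y axis), with grey circles for the 3 wild-type arrays, orange diamonds for the 3 35S:PCO1 arrays and an orange line at their mean. The groups do not overlap in any of these genes, and the wild-type arrays of AT1G62500 spread by an SD of 0.67.

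The level of PCO1 itself is not reported, because neither PCO1 nor the other PCO genes (PCO2 to PCO5) were paired with a probe set in the annotation used here. The transgene was therefore not checked against the labels. The largest difference of any probe set was that of 250152_at, which has no gene in that annotation and was singled out after its values were seen. It was 22.7-fold higher in 35S:PCO1, at 6.07 ± 0.26 in wild type and 10.6 ± 0.42 in 35S:PCO1 (log2, SD, n = 3 each, limma adjusted p = 3.07e-05). The sources used here do not say whether this probe set measures the PCO1 transgene, so its value is not read as a response to PCO1. Among other probe sets without a single gene, also chosen after their values were seen, 264007_at rose by 0.58, while 265948_at fell by 1.52 and 261335_at fell by 1.38. The calls of these last were lost with the trended robust prior (adjusted p = 0.179 for 265948_at and 0.140 for 261335_at).

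These calls rest on limma's moderated statistic with Benjamini-Hochberg adjustment over all tested probe sets, where 3043 probe sets had an unadjusted p under 0.05 (1339 higher, 1704 lower). The count depends strongly on single arrays: it was 489 without wild-type replicate 1 and 105 without 35S:PCO1 replicate 2, and 5 without wild-type replicate 2, without 35S:PCO1 replicate 1 or without 35S:PCO1 replicate 3. It was 0 with the ordinary t statistic (2472 at an unadjusted p under 0.05) and 2216 with array weights, where 965 were higher and 1251 lower, so that 56.5% were falls.

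The measured core hypoxia genes were on balance lower in 35S:PCO1 rosettes, although these plants were kept in air. Core hypoxia genes are transcripts that rise in many Arabidopsis tissues when oxygen is short. Of 49 genes written for this list 28 were measured, so the response as a whole was not assessed. Of these 28, 2 fell, 0 rose and 26 did not pass over all probe sets, while adjusted over the list alone 12 fell and 1 rose. The 2 were AT3G27220, a Kelch repeat gene (-0.67, SE 0.09, adjusted p = 0.0146), and AT4G10270 (-0.99, as above). The difference of AT1G19530 was -1.70 (SE 0.34, adjusted p = 0.0604), with wild-type arrays at 4.37, 5.47 and 6.13 and a 35S:PCO1 mean of 3.62 ± 0.07 (SD, n = 3). Its 35S:PCO1 arrays lay within the range of the dap and lys controls, 3.07 to 3.82, taken as the floor of the signal. This left little room to see a larger fall. That of AT3G03270, of the universal stress protein family, was -0.55 (SE 0.12, adjusted p = 0.0752), and without wild-type replicate 1 both AT1G19530 and AT3G03270 passed (adjusted p = 2.32e-04 and 0.00599). Over all settings their adjusted p ran up to 0.408 and 0.407, with the ordinary t statistic, and that of AT1G19530 was 0.259 with the trended robust prior. The 1 member higher over the list alone was AT1G05575 (0.27), and 22 members lay below 0 and 6 above. Both group means of AT5G10040, AT5G66985 and AT4G39675 lay within the range of the dap and lys controls, which leaves little room to see a fall.

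The mean difference of the hypoxia list was -0.23 and its median -0.15 on the log2 scale. The list passed the competitive test camera with a preset correlation of 0.01 between genes (adjusted p = 3.41e-07 over 9 lists). The call was lost with a correlation estimated from these arrays (camera p = 0.0770, or 0.618 adjusted over the 9 lists). The test fry, which asks whether the list's genes move one way and does not compare them with other genes, gave a p of 0.0378 (0.309 adjusted over the 9 lists). Relative to each gene's mean over the 6 arrays, the list mean was -0.022, 0.149 and 0.225 in wild-type replicates 1, 2 and 3 and -0.127, -0.088 and -0.136 in 35S:PCO1, or 0.117 ± 0.126 against -0.117 ± 0.025 (SD, n = 3 each). Hence the difference was larger than either group's SD but no larger than the range of the wild-type arrays, from -0.022 to 0.225. Of these, replicate 1 lay nearest to the 35S:PCO1 arrays. The 25S ribosomal RNA control probe set was lower in the same arrays (-1.26).

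**Figure D3:**
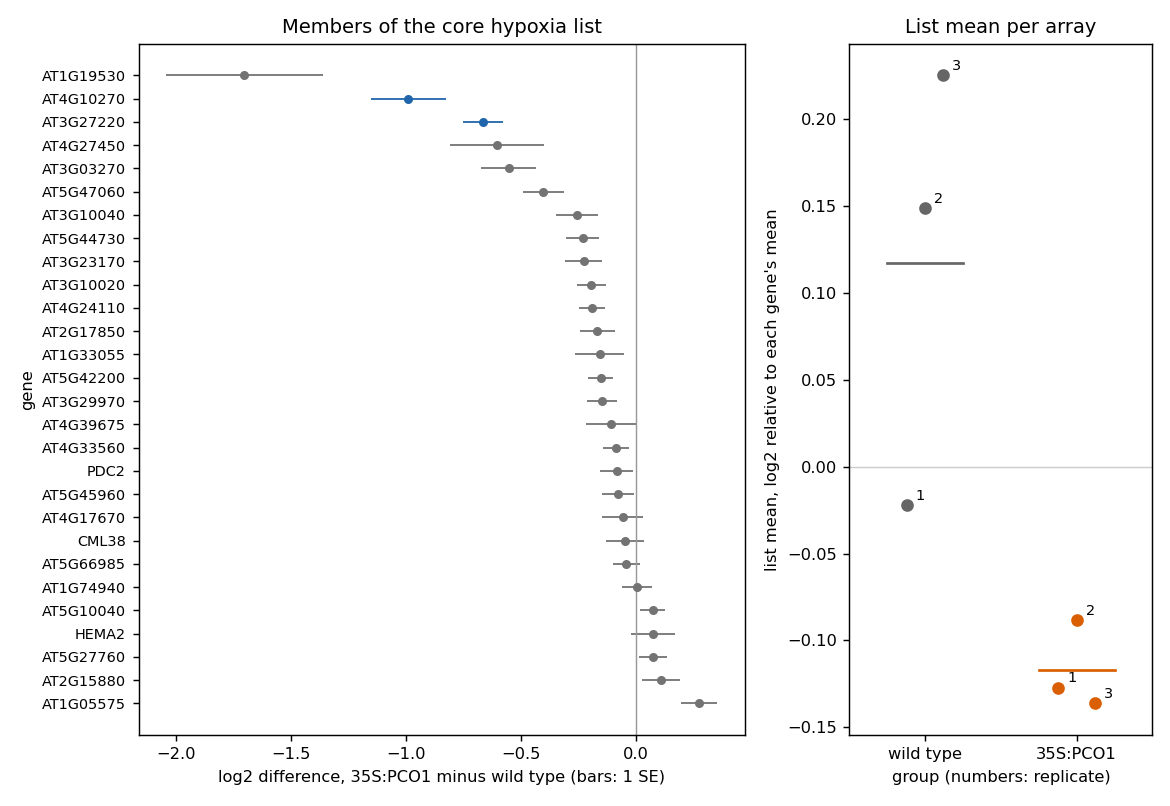
The left panel gives the log2 difference (35S:PCO1 minus wild type, x axis) of each of the 28 measured core hypoxia genes (y axis), with bars of 1 SE and the 2 genes past the adjusted p over all probe sets in blue. The right panel gives the list mean of each array (log2 relative to each gene's mean, y axis) by group, with the replicate number beside each point and a line at the group mean; the 3 wild-type arrays lie at -0.022, 0.149 and 0.225 and all 35S:PCO1 arrays lower.

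The measured genes of the fermentation list, the ERF-VII and N-degron list and the cysteine and sulfate list gave no call. Few were measured, with 3 of 10, 3 of 18 and 4 of 27 written genes, so the pathways as a whole were not assessed. Of the fermentation and sucrose breakdown list, 3 genes were measured: AT4G17260 (lactate dehydrogenase) differed by -0.11, PDC2 (pyruvate decarboxylase) by -0.09 and PPDK (pyruvate phosphate dikinase) by 0.04 (camera adjusted p = 0.518). Of the ERF-VII and N-degron list, AT2G44420 and AT2G41760, amidases of N-terminal residues, differed by -0.12 and -0.06, and MAP1A, a methionine aminopeptidase, by -0.02 (camera adjusted p = 0.399). Of the cysteine and sulfate list, the ATP sulfurylase genes APS4 and APS3 differed by 0.19 and -0.03, the sulfite reductase gene SIR by -0.17 and BGLU28 by -0.02 (camera adjusted p = 0.869). None of these 10 genes passed, over all probe sets or adjusted over the list alone.

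Of 15 genes written for the flavonoid and anthocyanin list, 4 were measured. These all had values above 0, and none passed. AT4G14090 (an anthocyanin glucosyltransferase) differed by 0.28, UF3GT (a further glycosyltransferase) by 0.22, DFR (dihydroflavonol reductase) by 0.22 and AT5MAT (a malonyltransferase) by 0.07, with a mean of 0.20 (camera adjusted p = 0.124, and 0.618 as the adjusted p with an estimated correlation). The list's value depended on single arrays: it passed without wild-type replicate 1 (mean 0.32, adjusted p = 8.99e-04), while without wild-type replicate 3 its mean was 0.054 (adjusted p = 0.965).

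No member of the other 4 tested lists passed over all probe sets. In the cold, drought and abscisic acid list, COR15A, COR15B, COR47 and LTI30 differed by 0.17, 0.13, 0.09 and -0.11 (camera adjusted p = 0.757). In the oxidative stress list, GSTU25, NDB2 and CCS differed by 0.05, -0.06 and 0.00024 (camera adjusted p = 0.869), and mean and median differed in sign. In the rapid touch and wound list, the zinc finger gene STZ differed by -0.42 (adjusted p = 0.163) and was lower adjusted over the list alone, while the calmodulin-like genes CML38 and CML37 differed by -0.05 and 0.04 (camera adjusted p = 0.399). The 4 measured reference genes, PEX4, AT4G26410, AT4G34270 and AT2G28390, differed by 0.07, -0.07, -0.03 and 0.02 (camera adjusted p = 0.882).

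Lists with fewer than 3 measured members had no list test. The 1 measured gene of the glucosinolate list, BCAT4, which starts the chain elongation of methionine, fell by 0.62 (SE 0.11, adjusted p = 0.0367). GRX480 of the salicylate list (0.33, adjusted p = 0.183) and PYE of the iron list (0.22) did not pass over all probe sets, though each passed adjusted over the list alone, where it was the 1 gene measured. The defence genes PDF1.2 and THI2.1 of the jasmonate list differed by 0.30 and 0.02, EIN3 and RTE1 of the ethylene list by 0.09 and 0.03, the clock gene GI by -0.03 and the heat shock gene ATHSP22.0 by -0.04. Of the photosynthesis list, RCA differed by 0.04 and LHCB4.1 by -0.04. Of the sugar starvation list, MCCA differed by -0.15 and MCCB by -0.14, and MCCB was lower adjusted over the list alone.

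Markers of other organs and stages were also compared, as the rosettes may hold other tissue. The root-expressed genes PYK10 and EXPA7 differed in opposite directions, by -0.45 (SE 0.15, adjusted p = 0.233) and 0.19 (SE 0.07, adjusted p = 0.257), and both passed adjusted over the list alone. PYK10 passed over all probe sets without wild-type replicate 3 (adjusted p = 0.0180). The senescence genes SAG101 and WRKY53 differed by 0.15 and 0.02. No member of the flower, seed storage or nitrate and phosphate starvation lists was measured.

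Among the control probe sets, that for 25S ribosomal RNA was 2.40-fold lower in 35S:PCO1, at 8.67 ± 0.20 in wild type and 7.41 ± 0.12 in 35S:PCO1 (log2, SD, n = 3 each). This difference of -1.26 (SE 0.10, limma adjusted p = 1.81e-04 over the 64 controls) ran between the groups in the same direction as the hypoxia list and most of the changed probe sets, and no other control probe set passed. Its values were 8.88, 8.66 and 8.48 in wild-type replicates 1, 2 and 3 and 7.39, 7.54 and 7.30 in 35S:PCO1, so that among the wild-type arrays it was highest in replicate 1, where the hypoxia list mean was lowest. The 5S ribosomal RNA probe set differed by 0.04. The mean 3' minus 5' log2 signal of 6 control probe set pairs for actin, GAPDH and ubiquitin, a measure of RNA integrity and labelling, was 0.761, 0.688 and 0.581 in wild-type replicates 1, 2 and 3 and 0.579, 0.628 and 0.547 in 35S:PCO1.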

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

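All alternatives were planned before the data were examined except the hypoxia list without its largest member. The count of changed probe sets (191; 47 higher, 144 lower) stayed within 1.5 times under both filters on dim probe sets, the 3 scalings and the trended robust prior (160 to 244). It became 2216 (965 higher, 1251 lower) with array weights, which put 4.55 on wild-type replicate 2 and 0.434 to 1.42 on the others, and 0 (0 higher, 0 lower) with the ordinary t statistic, where 2472 had an unadjusted p under 0.05. By construction a 2-fold minimum left 21 (2 higher, 19 lower) and an adjusted p under 0.1 gave 426 (115 higher, 311 lower). Leaving out 1 array gave 5 to 489 (2 to 98 higher, 2 to 391 lower). The cause of these shifts was not tested, beyond the fewer samples. With the replicate number as a block the count was 228, of which 155 were shared. Same-numbered arrays did not deviate together (r across probe sets -0.06, -0.08 and -0.02, and 0 arrays correlated best with their own number). The labels do not say whether same-numbered samples were grown or processed together. Of the 30 named probe sets past the threshold, calls were kept in 198 of 236 alternatives that leave out no array (the ordinary t statistic lost 30, and the trended robust prior 8: AT1G62500, AT3G21770, AT2G19970, AT3G18280, AT3G45160, AT2G28790, 265948_at and 261335_at, adjusted p from 0.0626 to 0.179) and in 77 of 180 that leave out 1. Of the 46 named genes not past the threshold, 9 passed with array weights (AT1G19530, AT3G03270, APS4, GRX480, AT4G14090, MCCB, STZ, PYK10 and EXPA7), 2 with the block (AT1G19530 and AT3G03270), 4 without wild-type replicate 1 (these 2, GRX480 and DFR) and 1 without wild-type replicate 3 (PYK10), 16 calls in all. For values not past the threshold a change of sign was not counted. The hypoxia list's shift of -0.23 lost its camera call with an estimated correlation (adjusted p = 0.618). For the same shift of -0.23 fry, which compares the list with no change and not with other genes, gave an adjusted p of 0.309. The camera call was kept under the block, both scalings run, the mean over probe sets and the filter (adjusted p = 0.00195), with each array left out (-0.30 to -0.18, adjusted p at most 1.61e-05), and without its largest member (-0.18, adjusted p = 2.43e-06). The mean over probe sets left the list's own value unchanged (-0.23), and the quantile scaling acted on values already quantile-normalized, so neither is a strong test. The flavonoid list, not called in the main test, passed under the block (0.20, adjusted p = 0.0223) and without wild-type replicate 1 (0.32, adjusted p = 8.99e-04), and its values with 1 array left out ran from 0.054 to 0.32. No other list changed its call. With the dimmest 40% dropped, 2 lists kept too few members for a test, and 4 of the 30 named probe sets were removed. The alternatives for the PCO1 level were not run, as no probe set is paired with it. Signals near 3.07 to 3.82, the range of the dap and lys controls, leave little room to see a fall, and GSTU25 and CML37 lay there on every array. Both group means of the hypoxia list members AT5G10040, AT5G66985 and AT4G39675 lay there too.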

Other observations

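The estimated correlation was planned, but its use as a test of a shared drift of the hypoxia genes, like the tests of the ribosomal RNA control, of the splits for the count of changed probe sets and of the pairs of wild-type arrays, was chosen only after the result was seen. Further changed genes, also chosen after their values were seen, include EXPB3, an expansin of the beta class, which fell by 0.72 (SE 0.08, limma adjusted p = 0.0116). UGT74B1, a glucosyltransferase of glucosinolate synthesis, fell by 0.45 (SE 0.05, adjusted p = 0.0116), and HL, a homologue of the yeast phosphatase HAL2, fell by 0.48 (SE 0.06, adjusted p = 0.0116). Families were also compared by the stem of the gene symbol, over 47 families with at least 5 measured genes. None held more changed genes than expected after adjustment (Fisher's exact test, two-sided). The lowest exact p was that of the tau class of glutathione S-transferases, where of 11 genes GSTU26 rose and GSTU20 fell (p = 0.00222, adjusted p = 0.104), followed by the beta-glucosidases, where of 20 genes BGLU46 and BGLU15 fell and 0 rose (adjusted p = 0.174). Both group means of BGLU46 (3.80 and 3.32) lay within the range of the dap and lys controls.

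The 25S ribosomal RNA control was 2.40-fold lower in 35S:PCO1, while plastid and mitochondrial transcripts differed little. Less RNA without a poly(A) tail in the labelled samples would lower both, yet the median difference of 87 organelle probe sets was -0.084 (quartiles -0.147 to 0.025, 0 past the threshold), far above the bound of -0.63 set for this test, midway to the 25S difference. The 18 hybridization controls had a median difference of -0.024. The values were quantile-normalized between arrays, which evens out array-wide differences, so these controls cannot show whether hybridization differed. The organelle test addresses the whole cause only. Less RNA from the 25S precursor, an altered cleavage of it or a handling step that acts on 25S alone may still be behind the value. No biological explanation was tested.

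The measured core hypoxia genes were on balance lower in 35S:PCO1. A shift of all genes of that signal level is argued against, since 0 of 10000 random lists matched on signal had a mean as low (-0.23 against a lowest random mean of -0.137). What stays open is that genes of one regulon drift together between plants: the call was lost with the estimated correlation (adjusted p = 0.618). The real split had a camera p of 3.79e-08, 1 of 10 splits with a p as small, against 4.63e-07 for the next (list mean -0.19, of which -0.08 is carried over from the real difference by construction), and 10 splits are too few for a share under 0.05. An effect of the genotype was not tested beyond these values and stays open.

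Falls outnumbered rises in 35S:PCO1, and the share of falls was at least 69.7% when the deposited values were scaled again in 3 ways. As these values were already quantile-normalized, this cannot show whether the original scaling made the imbalance. Leaving out 1 array gave a share as low as 40%, but over 5 calls, and 74.3% to 80.0% for the 3 arrays whose omission left 20 calls or more, so that this test cannot settle whether 1 array drives it. A state of the plants that also varied among the wild-type samples, such as growth, may contribute: of the 144 lower probe sets, 81.9% were lower in wild-type replicate 1 than in replicate 3, the highest of the 3 pairs (77.1% and 73.6% in the others), where 56.9% of all probe sets were. The pairs cannot tell a plant state from RNA integrity or labelling, as the mean 3' minus 5' signal also fell from wild-type replicate 1 to 3 (0.761, 0.688 and 0.581). In 35S:PCO1 that signal (0.579, 0.628 and 0.547) lay nearer to wild-type replicate 3 than to replicate 1. Among the wild-type arrays most of the lower probe sets were higher where that signal was lower, which would place them higher in 35S:PCO1. This argues against RNA integrity or labelling, as far as that signal measures them, as the cause of the falls between the groups. What varied among the wild-type arrays stays open. The real split gave 191 changed probe sets and the highest of the others 0, so it was 1 of 10 with as many. Every other split mixes the 2 groups on each side, so differences between the groups widen its spread. A low count there follows largely by construction, and 10 splits are too few for a share under 0.05. An effect of PCO1 itself on these genes remains open.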
